A study of Danio rerio with 32 samples.

How the data were processed

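Total RNA of whole zebrafish embryos, 60 to 100 per sample, was isolated with a Qiagen kit and checked on a Bioanalyzer, per the labels. The labels give 50 to 100 pg of injected Klf2a, Klf2b or FoxD3 mRNA per embryo and 15 µg/ml cycloheximide from 1.5 to 4.7 hours after fertilisation, and no dose for GFP mRNA. Each of the 16 arrays carried 2 samples, 1 in Cy3 and 1 in Cy5, and the duplicates of a group had different dyes. Per the file headers the spot values are intensity readings of Agilent Feature Extraction 10.7.3.1, with spot and local background medians that are not corrected, processed signals that the scanner software corrected for background and dye, and other columns that hold flags of 0 or 1 per spot. The authors' values, in a table of 43663 probes, are intensity on a linear scale after the authors' quantile normalisation over the 32 channels, which the labels say were split in Genedata Analyst and compared independently. Every column of that table had a median of 119.06, and each column correlated best with its own channel in the scanner files (r of at least 0.997, against at most 0.991 with any other channel, in all 32 samples).

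The grouping, lists, comparisons, alternatives and rule for named genes were fixed before the data were examined. They assumed mean spot signals, but the files hold medians, so median spot signal and median background were used. Of 45220 spots 1417 were controls, and the 43803 others made up 43603 probes. Gene symbols were found for 25258 probes (12955 distinct symbols), and the other 18345 kept the name in the file. Spots marked as not uniform or as outlying by the scanner software were left out, and 0 were saturated. Signals were corrected with limma's normexp (offset 50), taken to log2 and quantile-normalised over the 32 channels. Probes well above background in both samples of at least 1 group were kept (34259), and each gene was represented by its probe with the highest mean, which gave 22511 genes. In 4 of the probes some group had no value.

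limma 3.58.1 (R 4.3.3, statmod 1.5, data.table version 1.17.8) fitted 16 group means and a dye term, with the 2 samples of an array as a random block (correlation 0.137), and moderated the variances with a trend (15 residual and 5.40 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, in a two-sided moderated test, separately in each comparison. The comparisons were MZspg against WT, cycloheximide against none, each factor against GFP in both genotypes with and without cycloheximide, Klf2a against Klf2b, and the interactions of genotype with cycloheximide and with each factor. The test assumes that groups of 2 share a variance structure, and a single comparison of 2 against 2 samples could not pass a permutation test. Slide could not be a term for comparisons that lie on different slides. Overlaps between comparisons were tested with Fisher's exact test, one-sided. Correlations and covariances between comparisons were set beside 20 simulated draws of unchanged groups.

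For 19 lists camera, in limma, tested whether the members moved against all other genes, with a preset correlation of 0.01 and, as an alternative, with the correlation estimated from the residuals, and the p values were adjusted over the 19 lists of a comparison. The lists are the injected and target genes, the enveloping layer, the Klf family, ventral and ectodermal, dorsal organiser, mesendoderm, neural, Pou5f3-dependent regulators, yolk syncytial layer, maternal and oocyte, germ plasm, p53 and apoptosis, immediate early, stress, cell cycle, adhesion and epiboly, ribosomal, housekeeping, and blood, vessel and muscle. Some share members (klf17 is in 4 of them), so they are not independent of each other. The ribosomal list was set by a name pattern and also holds S6 kinase genes such as rps6ka4. The Pou5f3-dependent list came from general knowledge of the mutant and not from these samples.

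Named genes are the injected and target genes in every comparison, up to 10 called genes each way with the largest change for genotype and cycloheximide, and up to 5 each way for injections, factor pairs and interactions. These had to have a gene symbol and, except in interactions, samples that did not overlap between the groups. From each list up to 4 members with the largest moderated statistic were eligible. Where both samples of 1 group were not well above background, a fold is given as "at least", computed against the lowest well-measured signal of the samples (5.66 to 6.48 log2). Rose, fell, higher and lower are used of genes that passed.

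Alternatives were processed signals, loess within and quantile between arrays, scaling to the 75th percentile, no filter (29146 genes), no dye term, independent samples of an array, a term for replicate number, the authors' values, a fit of each slide alone, other lists for the medians, and each sample left out in turn, where the lone sample is assumed to vary like the other groups. In simulated data with 200 changed genes, 12% of changes of 0.5 log2, 74% of 1, 96% of 2 and 100% of 3 were recovered in the Klf2a comparison of MZspg under cycloheximide, with 9 false calls of 150, and 0 genes were called in an unchanged comparison. For MZspg against WT the shares were 16, 70, 94 and 100%, with 5 false calls of 145. Other columns of the scanner files were not used.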

Results

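Zebrafish embryos were injected with mRNA for green fluorescent protein (GFP), Klf2a, Klf2b or FoxD3 and frozen at 4.7 hours after fertilisation, at 30% epiboly. Klf2a and Klf2b are Krüppel-like transcription factors, and FoxD3 is a forkhead repressor. The embryos were wild type (WT) or MZspg, which lack both maternal and zygotic function of the stem-cell-type factor Pou5f3. Each genotype and injection was studied with and without cycloheximide, an inhibitor of protein synthesis, which gave 16 groups of 2 samples and 32 samples in all. Every sample pooled 60 to 100 embryos and occupied 1 colour of a 2-colour array, on 16 arrays of 4 slides. Well-measured spots, those well above local background, numbered 23733 to 32550 per sample, or 54.2 to 74.3% of the probe spots, and 0 spots were saturated. Duplicates had Pearson's r of 0.973 to 0.996 across genes, which are not independent replicates, and the number of arrays limits the precision. Values below are log2 differences ± standard error of the fit, with 2 samples per group, or 1 where a flagged spot was left out. Lists of genes get 2 adjusted p values, from a preset and from an estimated correlation between genes, and their directions are relative to all genes tested.

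Each injected transcript was followed by 1 of its 2 probes. The foxd3 probe with the higher mean signal rose with FoxD3 mRNA in WT (4.92 ± 0.28, adjusted p = 1.99e-11) and in MZspg (8.82 ± 0.28, adjusted p = 4.17e-15), and under cycloheximide by 5.38 ± 0.28 in WT and 9.13 ± 0.28 in MZspg. A second foxd3 probe did not rise, with -0.39 ± 0.21 in WT and -2.33 ± 0.21 in WT with cycloheximide, and in MZspg 0 of its FoxD3 samples were well above background, so no change is given there. The klf2a probe with the higher mean signal rose with Klf2a against GFP only in MZspg under cycloheximide (1.28 ± 0.27), with 0.02 ± 0.27 in WT, and that of klf2b rose with Klf2b in no setting (0.22 ± 0.15 in WT). A second klf2a probe rose with Klf2a against GFP by 3.43 ± 0.20 in WT, 2.57 ± 0.20 in WT with cycloheximide and 3.14 ± 0.20 in MZspg with cycloheximide. In MZspg without the drug, where slides differ, it did not pass (0.38 ± 0.20, adjusted p = 0.123). It was higher with Klf2a than with Klf2b in all 4 settings, by 2.67 ± 0.19 in WT, 2.47 ± 0.19 in WT with cycloheximide, 2.73 ± 0.19 in MZspg and 2.74 ± 0.19 in MZspg with cycloheximide. A second klf2b probe rose with Klf2b against GFP by 5.08 ± 0.26 in WT, 3.85 ± 0.26 in WT with cycloheximide, 4.85 ± 0.26 in MZspg, where only 1 GFP sample was well above background, and at least 34.3-fold in MZspg with cycloheximide. The m793 change in MZspg is a point mutation, so the pou5f3 transcript level says nothing of the protein.

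The 8 samples of slide 1, the GFP groups of both genotypes and the WT Klf2a and Klf2b groups, all without cycloheximide, stood apart. For 940 genes all 8 lay over 1 log2 unit away from all 24 other samples, 605 genes above and 335 below. The same count was 1 gene for slide 2 and 0 for slides 3 and 4, and 0 genes parted the 16 cycloheximide samples from the 16 others in this way. Different probes of 1 gene also went apart on slide 1. Over 7310 genes with several probes, the first component of the within-gene probe differences held 65.7% of their variance, and slide 1 scored 0.237 to 0.365 against -0.140 to -0.0145 elsewhere. A second pou5f3 probe gave -3.60 ± 0.22 for Klf2a against GFP in MZspg, where the first gave -0.02 ± 0.20. For comparisons that set slide 1 against another slide the share of genes with conflicting probes is therefore given. Where a treatment and its control lie on different slides, slide and treatment cannot be told apart.

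**Figure D1:**
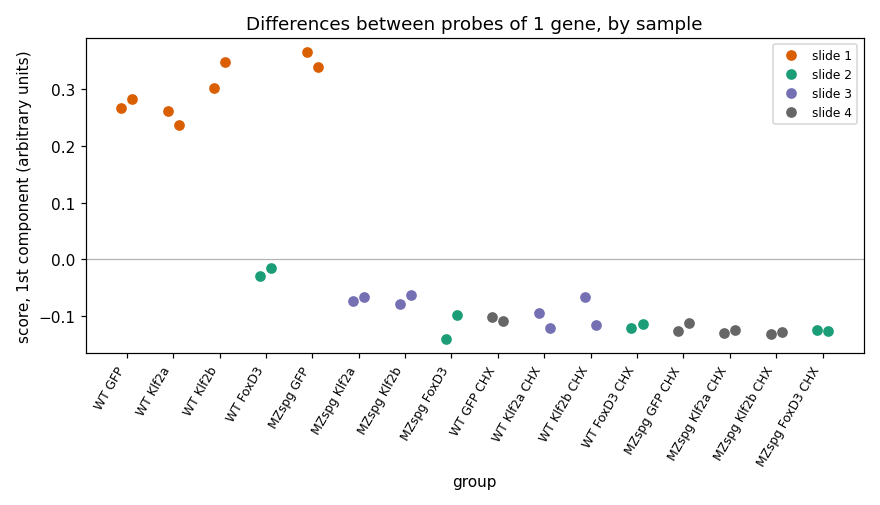
Each point is 1 sample, with its group along the x axis, its slide as colour and its score on the first component of within-gene probe differences (arbitrary units) on the y axis. The 8 samples of slide 1 score 0.237 to 0.365, above the 24 others at -0.140 to -0.0145.

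MZspg embryos were compared with WT embryos, both GFP-injected and on slide 1, to ask which transcripts depend on Pou5f3. In MZspg, 4211 genes were higher and 3844 lower of 22511 tested (1262 and 1526 by at least 2-fold). The regulators klf17, an enveloping-layer factor (-3.90 ± 0.22, adjusted p = 7.12e-11), foxd3 (-2.46 ± 0.26, adjusted p = 5.17e-07) and pou5f3 itself (-1.94 ± 0.19) fell, klf2a rose (0.89 ± 0.26, adjusted p = 0.00932) and klf2b did not pass (0.29 ± 0.14, adjusted p = 0.119). The fall of klf17 was at least 14.5-fold. The largest falls were sult6b1 (-5.73 ± 0.34), the keratin gene krt99 (-5.20 ± 0.25), slc2a12 (-5.01 ± 0.49), acer1 (-4.69 ± 0.34) and sp5l (-4.64 ± 0.50). The complement factor gene cfd (5.02 ± 0.44), tp53rk (4.36 ± 0.71), prkcq (4.36 ± 0.66), sccpdha.2 (4.22 ± 0.79) and the phosphatase gene dusp14 (4.19 ± 0.91) rose most.

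Genes of the enveloping layer, the outer epithelium of the embryo, were lower in MZspg. Of 20 measured, 0 rose, 17 fell and 3 did not pass (0 and 18 adjusted over the list alone), with a median of -2.20 (adjusted p = 1.27e-20 preset, 0.000575 estimated). Examples are evpla, which encodes an envoplakin (-3.87 ± 0.27), and the keratin genes krt17 (-3.65 ± 0.27), cyt1l (-3.31 ± 0.26) and krt5 (-4.04 ± 0.48). Among 9 regulators known to depend on Pou5f3, 1 rose, 7 fell and 1 did not pass (1 and 7 adjusted over the list alone), including mych (-3.83 ± 0.26) and hesx1 (-1.57 ± 0.11) (adjusted p = 1.22e-14 preset, 8.85e-11 estimated). That list shares klf17 with the enveloping-layer list and others with the neural list, so these are not independent. Dorsal organiser genes gave 1 up and 8 down of 17 (2 and 9 adjusted over the list alone), with the Wnt inhibitor gene dkk1b at -1.80 ± 0.24 (adjusted p = 0.00295 preset, 0.0689 estimated). Mesendoderm genes were 2 up and 13 down of 22 (2 and 15 adjusted over the list alone), such as fgf24 (-2.71 ± 0.21), msgn1 (-2.27 ± 0.26) and mixl1 (-1.78 ± 0.28) (adjusted p = 0.000285 preset, 0.172 estimated). Neural genes went both ways, 6 up and 9 down of 24, with a median of 0.07 against a test that points down (adjusted p = 0.0422 preset, 0.21 estimated). Their largest falls were sox11a (-3.09 ± 0.24) and sox2 (-3.16 ± 0.33, at least 8.96-fold). Adhesion and epiboly genes were 1 up and 5 down of 14, led by the planar-polarity gene prickle1b (-3.27 ± 0.20) and the cadherin gene cdh2 (-2.27 ± 0.22) (adjusted p = 0.00109 preset, 0.00123 estimated).

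Maternal and oocyte transcripts were higher in MZspg, where 7 rose and 0 fell of 15 (9 and 0 adjusted over the list alone, adjusted p = 0.000912 preset, 0.0083 estimated). Among them were dazl, an RNA-binding germ-line factor (1.41 ± 0.17), the meiotic kinase gene mos (2.15 ± 0.27) and the oocyte histone gene h1m (1.34 ± 0.18). The tests of the ventral (4 up, 9 down of 25, adjusted p = 0.303), yolk syncytial (1 and 4 of 11, adjusted p = 0.112), immediate-early (10 and 5 of 26, adjusted p = 0.303) and p53 genes (1 and 3 of 9, adjusted p = 0.643) did not pass. Neither did those of the Klf family (4 and 4 of 18, adjusted p = 0.572), germ plasm (2 and 1 of 8, adjusted p = 0.954), stress (4 and 1 of 13, adjusted p = 0.303) and cell-cycle genes (0 and 3 of 18, adjusted p = 0.908). Ribosomal (4 up and 9 down of 85, adjusted p = 0.267), housekeeping (2 and 1 of 8, adjusted p = 0.637) and blood, vessel and muscle genes (3 and 0 of 10, adjusted p = 0.201) were not shifted past the test either. Within slide 1 alone 6394 genes passed, and without MZspg GFP replicate 1 the count was 4950. Of the genes with 2 or more passing probes, 11.4% had probes that passed in opposite directions. Of 3204 called genes with more than 1 probe, 1880 had a probe that did not pass.

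Under cycloheximide the same genotypes, GFP-injected on slide 4, were compared to ask which differences stand when proteins made after 1.5 hours are blocked. In MZspg 2329 genes were higher and 2047 lower. The falls of klf17 (-4.20 ± 0.22, adjusted p = 7.13e-11) and foxd3 (-2.77 ± 0.26, adjusted p = 2.31e-07) were there too, and klf2a now fell (-2.22 ± 0.26, adjusted p = 3.06e-06), while klf2b did not pass (-0.12 ± 0.14, adjusted p = 0.679). The largest falls were lfng (-5.71 ± 0.31), nnr (-5.63 ± 0.34), aplnrb (-5.30 ± 0.29), znfl1b (-5.02 ± 0.35) and sult6b1 (-4.92 ± 0.34). The largest rises were gbgt1l4 (5.00 ± 0.50), sccpdha.2 (4.41 ± 0.79), faima (4.20 ± 0.73), tp53rk (3.41 ± 0.71) and tmed1b (3.31 ± 0.69). Both with and without the drug 997 genes rose (436 expected from independence) and 1120 fell (350), while 73 and 101 went opposite ways. The comparisons share no sample, and their r across genes was 0.511 (-0.0018 in simulated unchanged groups).

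Early zygotic genes of several germ layers were lower in MZspg under cycloheximide. Ventral and ectodermal genes gave 2 up and 12 down of 25, such as the transcription factor genes ved (-3.94 ± 0.22), gata2a (-3.94 ± 0.27) and tfap2a (-3.96 ± 0.32) and the signal gene bmp2b (-2.53 ± 0.24) (adjusted p = 4.45e-10 preset, 0.00198 estimated). Of 17 dorsal genes 0 rose, 11 fell and 6 did not pass (1 and 11 adjusted over the list alone), with noto at -3.17 ± 0.49, foxa3 at -2.51 ± 0.41 and cxcr4b at -2.93 ± 0.26 (adjusted p = 1.49e-08 preset, 0.000168 estimated). In mesendoderm 1 rose and 13 fell of 22, including cxcr4a (-3.30 ± 0.27), mixl1 (-2.53 ± 0.28) and the Nodal inhibitor gene lft2 (-2.08 ± 0.24) (adjusted p = 1.05e-11 preset, 0.00294 estimated). Neural genes were 0 up and 8 down of 24 (0 and 9 adjusted over the list alone), with her3 at -3.87 ± 0.46 and sox19a at -2.63 ± 0.32 (adjusted p = 2.75e-06 preset, 0.00198 estimated). The Pou5f3-dependent regulators (0 up, 5 down, adjusted p = 1.04e-12 preset, 1.25e-09 estimated) and adhesion genes (1 up, 5 down of 14, with 3 and 6 adjusted over the list alone, adjusted p = 1.14e-05 preset, 1.7e-05 estimated) were also lower. For adhesion the median was only -0.06, with has2 at -3.11 ± 0.31 and jupa at -3.65 ± 0.38.

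Fewer enveloping-layer genes passed here, 0 up and 7 down of 20, with krt18a.1 at -2.09 ± 0.42 and the claudin gene cldnb at -2.53 ± 0.51 (adjusted p = 2.92e-05 preset, 0.13 estimated). In the p53 list 0 rose and 4 fell of 9 (0 and 7 adjusted over the list alone), with bbc3 at -2.30 ± 0.39 (adjusted p = 0.000212 preset, 0.123 estimated). Ribosomal genes, with 11 up and 2 down of 85 (adjusted p = 0.00183 preset, 0.48 estimated), and yolk syncytial genes, with 1 up and 3 down of 11 (adjusted p = 0.0419 preset, 0.269 estimated), did not hold with the estimated correlation. Leaving out WT replicate 1, WT replicate 2 or MZspg replicate 1 of these groups gave 2066, 2655 and 2214 genes, and the within-slide fit 5929.

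The difference between both genotype effects was tested as an interaction, and 3352 genes passed (1696 up, 1656 down). Slide differences cancel in it only if they are alike in both genotypes, and 4.34% of testable genes had probes that disagreed. The klf2a effect differed (-3.12 ± 0.36, adjusted p = 8.29e-06). Enveloping-layer genes, lower in MZspg without the drug, had more positive genotype effects under cycloheximide in 13 of 20 cases and less positive ones in 0, as for krt17 (3.63 ± 0.38) and evpla (3.66 ± 0.39). The list test did not hold with the estimated correlation (adjusted p = 4.32e-10 preset, 0.101 estimated), and krt17 and evpla were near background in both genotypes under cycloheximide. The effect on sox2 (3.40 ± 0.46) and the segmentation gene her1 (4.10 ± 0.50) was also less negative with the drug, and that on lfng (-5.45 ± 0.43), aplnrb (-5.16 ± 0.41) and gata2a (-3.50 ± 0.38) more negative. The ventral list gave 3 up and 8 down (adjusted p = 0.000548 preset, 0.171 estimated). Leaving out MZspg GFP replicate 1 gave 1814 genes, and leaving out WT GFP replicate 2 gave 2074. Without MZspg replicate 1, WT replicate 1 or WT replicate 2 of the cycloheximide GFP groups the counts were 1944, 1793 and 2039.

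**Figure D2:**
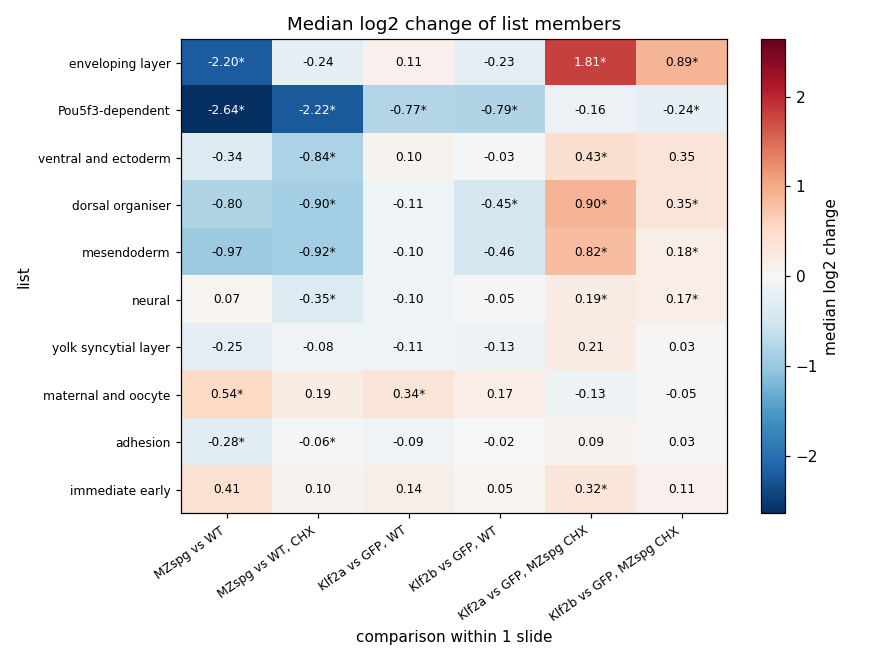
Each square gives the median log2 change of the members of a list (y axis) in a comparison within 1 slide (x axis), with 2 samples per group, and a star marks lists that pass the test with an estimated correlation. The enveloping-layer median is -2.20 in MZspg against WT and 1.81 with Klf2a against GFP in MZspg under cycloheximide.

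Klf2a and GFP mRNA were compared in MZspg embryos under cycloheximide, on slide 4, to ask which transcripts respond to Klf2a without newly made intermediates and without Pou5f3. Klf2a raised 551 genes and lowered 321 (381 and 113 by at least 2-fold). The keratin genes krt5 (6.54 ± 0.51, adjusted p = 6.56e-08), krt4 (6.02 ± 0.38, adjusted p = 4.31e-09) and krt97 (5.92 ± 0.41, adjusted p = 9.96e-09) rose most, followed by lfng (4.66 ± 0.33) and aplnrb (4.32 ± 0.31). The Klf2a duplicates differed widely, with SDs of 1.30 for krt5, 0.90 for krt4 and 0.99 for lfng. The standard errors rest on all groups and do not show this. The apolipoprotein gene apoeb (-2.70 ± 0.36), mpc2a (-2.59 ± 0.16), ndrg3a (-2.25 ± 0.26) and rnf144b (-2.25 ± 0.38) fell most. Among the regulators klf2a rose (1.28 ± 0.27, adjusted p = 0.00818), foxd3 (-1.44 ± 0.28, adjusted p = 0.00398) and klf17 (-1.17 ± 0.23, adjusted p = 0.00435) fell, and klf2b (0.20 ± 0.15, adjusted p = 0.656) and pou5f3 (0.58 ± 0.20, adjusted p = 0.141) did not pass. A second foxd3 probe lay at 6.42 log2 with GFP and 6.43 with Klf2a. For it and for klf17 only 1 Klf2a sample was well above background. The GFP samples shared their arrays with WT GFP, and the Klf2a samples with Klf2b.

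Of 20 enveloping-layer genes 11 rose, 1 fell and 8 did not pass (13 and 2 adjusted over the list alone), with a median of 1.81 (adjusted p = 2.17e-36 preset, 1.64e-06 estimated), and evpla was at least 10.8-fold higher. Mesendoderm genes rose, 12 up and 0 down of 22 (13 and 0 adjusted over the list alone), with cxcr4a at 2.82 ± 0.29, mixl1 at 2.49 ± 0.31 and lft2 at 1.91 ± 0.25 (adjusted p = 6.15e-23 preset, 1.91e-05 estimated). Dorsal genes gave 8 up and 0 down of 17, including noto (3.59 ± 0.53), foxa3 (3.01 ± 0.44) and goosecoid, gsc (1.96 ± 0.42) (adjusted p = 3.39e-12 preset, 4.39e-06 estimated). The ventral list held 9 rises and 0 falls of 25 (12 and 0 adjusted over the list alone), such as gata2a (4.09 ± 0.29), ved (2.95 ± 0.30) and bambia (2.07 ± 0.32) (adjusted p = 9.71e-14 preset, 0.000154 estimated). For ved and bambia only 1 Klf2a sample had a value. Neural genes were 9 up and 0 down of 24, with her5 at 3.26 ± 0.42 and sox3 at 2.50 ± 0.39 (adjusted p = 3.23e-09 preset, 9.4e-05 estimated). Immediate-early genes (6 up and 0 down of 26, 11 and 0 adjusted over the list alone) included dusp6, a feedback phosphatase of FGF signalling (2.68 ± 0.35) (adjusted p = 1.67e-07 preset, 0.0159 estimated). Stress genes (3 up and 0 down of 13, adjusted p = 0.00384 preset, 0.0159 estimated) included ddit3 (1.85 ± 0.30), and cell-cycle genes (4 up and 0 down of 18, adjusted p = 0.00224 preset, 0.0175 estimated) included the cyclin gene ccnd1 (3.18 ± 0.44).

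In the Klf family 5 rose and 2 fell of 18, with klf6a at 1.46 ± 0.25 and klf3 at 1.43 ± 0.26 (adjusted p = 0.0487 preset, 0.262 estimated). The p53 list gave 1 up, sesn1 (1.95 ± 0.42), and 0 down (adjusted p = 0.038 preset, 0.431 estimated). For sesn1 only 1 Klf2a sample had a value. Pou5f3-dependent regulators (1 up and 2 down of 9, adjusted p = 0.46), yolk syncytial (2 and 1 of 11, adjusted p = 0.305), adhesion (1 and 0 of 14, adjusted p = 0.127), ribosomal (0 and 0 of 85, adjusted p = 0.993) and germ plasm genes (0 and 0 of 8, adjusted p = 0.993) did not pass as lists. The fit within slide 4 alone, with 3 residual degrees of freedom, passed 84 genes, and without GFP replicate 1 or Klf2a replicate 2 the counts were 301 and 533. Of the genes with several passing probes 0% had probes that disagreed. However, of 360 called genes with more than 1 probe, 212 had a probe that did not pass.

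In WT embryos under cycloheximide, Klf2a (slide 3) was compared with GFP (slide 4), and 110 genes rose and 12 fell. Keratin and envelope genes again rose most, krt5 (5.89 ± 0.51, adjusted p = 1.15e-06), krt4 (4.39 ± 0.38), krt97 (3.92 ± 0.41), evpla (3.67 ± 0.29, at least 12.1-fold) and the calpain gene capn9 (3.64 ± 0.39). Among genes with a symbol and separated samples, the largest falls were sulf2a (-1.44 ± 0.31), ugt2a5 (-0.74 ± 0.16) and tat (-0.70 ± 0.16). Of 20 enveloping-layer genes 8 rose, 0 fell and 12 did not pass (9 and 0 adjusted over the list alone) (adjusted p = 3.07e-52 preset, 2.41e-09 estimated), with krt8 at 3.31 ± 0.32. The Klf family gave 3 up and 0 down, among them klf3 (2.66 ± 0.26) and klf13 (1.04 ± 0.22) (adjusted p = 8.9e-07 preset, 0.00364 estimated). The ventral list gave 2 up and 0 down, bambia (1.74 ± 0.26) and gata2a (1.73 ± 0.29) (adjusted p = 0.000512 preset, 0.224 estimated). In cell-cycle genes ccnd1 was higher (2.50 ± 0.44). The Klf2a effects under cycloheximide in WT and MZspg, which share no sample, had 59 rises and 4 falls in common against 2.69 and 0.171 expected (Fisher's exact test, p = 9.04e-66 for the rises). Their GFP samples were the 2 colours of the same arrays, so the effects are not fully independent. Leaving out GFP replicate 1, GFP replicate 2 or Klf2a replicate 2 gave 79, 44 and 65 genes.

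**Figure D3:**
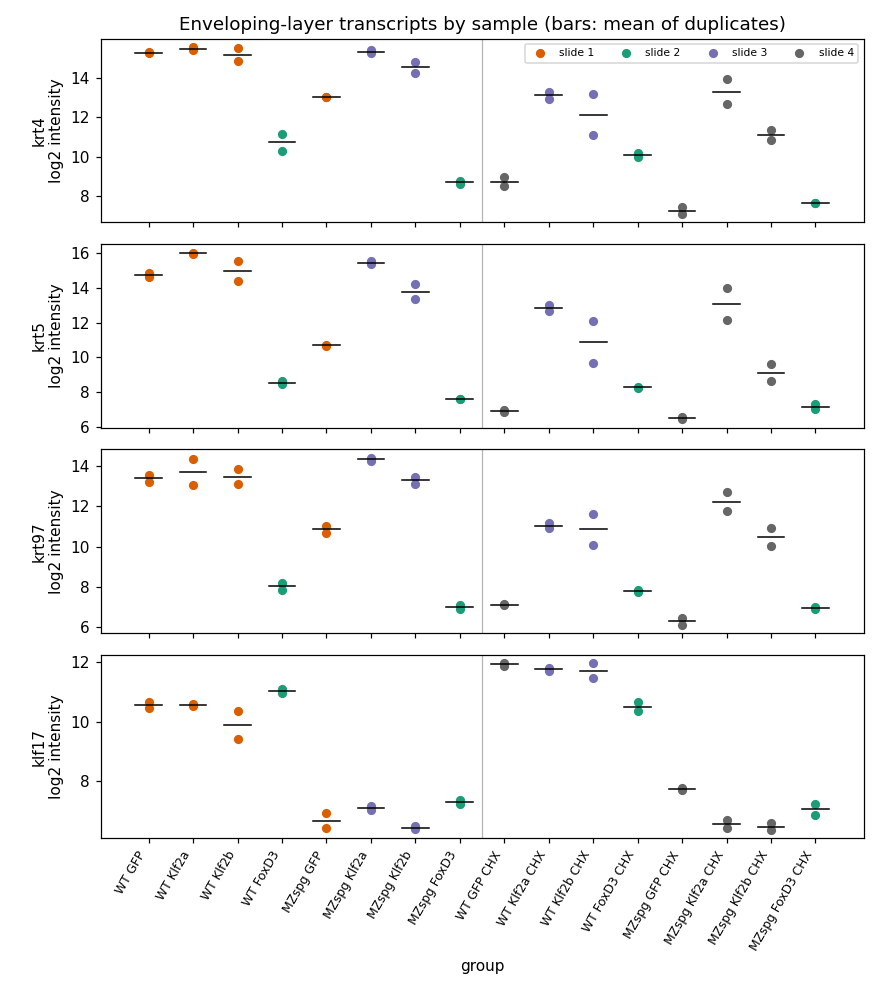
Each point is 1 sample and each bar the mean of 2 duplicates, with the group on the x axis, the slide as colour and the normalised log2 intensity of krt4, krt5, krt97 or klf17 on the y axes. Under cycloheximide krt4 lies at 7.11 and 7.46 with GFP and at 12.66 and 13.93 with Klf2a in MZspg embryos.

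Without cycloheximide Klf2a and GFP were compared in WT on slide 1, where 686 genes rose and 417 fell. The largest rises were ociad2 (5.02 ± 0.36), the annexin gene anxa2a (4.95 ± 0.51, at least 30.9-fold), icn (4.24 ± 0.47) and arl3l1 (4.14 ± 0.50). The largest falls were sp5l (-2.50 ± 0.54), dhrs3b, a gene of retinoid metabolism (-2.13 ± 0.27), klhl41b (-2.01 ± 0.54) and her7, of the segmentation clock (-1.84 ± 0.45). In the Klf family 3 rose and 0 fell of 18 (7 and 0 adjusted over the list alone), klf4 (2.85 ± 0.25, adjusted p = 2.06e-07), klf3 (1.40 ± 0.26) and klf11a (1.38 ± 0.27) (adjusted p = 0.000238 preset, 0.0446 estimated). Pou5f3-dependent regulators gave 0 up and 5 down of 9, including sox2 (-1.67 ± 0.35) and foxd3 (-1.02 ± 0.28, adjusted p = 0.041) (adjusted p = 0.000238 preset, 0.00488 estimated). Maternal genes were 2 up and 0 down of 15 (5 and 0 adjusted over the list alone), with btg4, which speeds mRNA decay, at 2.13 ± 0.43 (adjusted p = 0.00784 preset, 0.0446 estimated). Enveloping-layer genes were 0 up and 0 down of 20 in the limma test (0 and 0 adjusted over the list alone, adjusted p = 0.312), with krt5 at 1.23 ± 0.51, adjusted p = 0.19. The ventral list gave 4 rises, among them the BMP feedback gene szl (2.49 ± 0.20) and the epidermal gene tp63 (1.67 ± 0.25), and 1 fall (adjusted p = 0.0576), and mesendoderm 0 rises and 3 falls (adjusted p = 0.186). The fit within slide 1 passed 215 genes, scaling to the 75th percentile 98, and leaving out GFP replicate 1, GFP replicate 2 or Klf2a replicate 2 gave 708, 314 and 354.

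In MZspg without cycloheximide Klf2a was on slide 3 and GFP on slide 1, and 12334 genes passed (6911 up, 5423 down). Of the genes with several passing probes 42.6% had probes that disagreed, and slide and injection cannot be told apart. Enveloping-layer genes were 15 up and 1 down of 20, with krt94 at 4.68 ± 0.18, krt5 at 4.73 ± 0.51 and evpla at 4.13 ± 0.29 (adjusted p = 0.000109 preset, 0.836 estimated). The largest rises were cavin2b (6.01 ± 0.27), pde6hb (5.32 ± 0.24) and icn (5.22 ± 0.47) and the largest falls ano10b (-6.94 ± 0.20) and plp2b (-6.78 ± 0.22). Shared with the cycloheximide comparison were 317 rises (169 expected) and 65 falls (77.3 expected, p = 0.956, Fisher's exact test), and 74 genes rose here and fell there and 55 the reverse. In WT 38 rises were shared (3.35 expected, p = 5.66e-30, Fisher's exact test) and 1 fall.

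Klf2b and GFP were compared in MZspg under cycloheximide on slide 4, with 77 genes up and 97 down. The largest rises were krt97 (4.16 ± 0.41, adjusted p = 4.4e-06), krt4 (3.81 ± 0.38, adjusted p = 6.06e-06), the apelin receptor genes aplnra (2.88 ± 0.27) and aplnrb (2.87 ± 0.31) and gata2a (2.74 ± 0.29). The largest falls were apoeb (-3.47 ± 0.36), the synaptonemal gene sycp1 (-3.09 ± 0.64), ndrg3a (-2.38 ± 0.26) and nudt22 (-2.29 ± 0.51), and foxd3 (-1.89 ± 0.28, adjusted p = 0.000848) and klf17 (-1.27 ± 0.23, adjusted p = 0.00695) fell as well. For klf17 only 1 Klf2b sample was well above background, and for nudt22 only 1 Klf2b sample had a value. A second foxd3 probe lay at 6.42 log2 with GFP and 6.17 with Klf2b, where 0 samples were well above background. Of 20 enveloping-layer genes 5 rose, 1 fell and 14 did not pass (10 and 2 adjusted over the list alone) (adjusted p = 3.09e-13 preset, 0.013 estimated). Neural genes gave 3 up and 0 down of 24 (6 and 0 adjusted over the list alone), with her5 at 2.07 ± 0.42 and sox11a at 1.30 ± 0.26 (adjusted p = 2.12e-06 preset, 0.00736 estimated). The mesendoderm list gave 2 up and 0 down of 22 (5 and 0 adjusted over the list alone, adjusted p = 1.4e-06 preset, 0.0475 estimated), with cxcr4a at 1.35 ± 0.29. In the dorsal list 0 rose and 0 fell in limma's test of each gene (4 and 0 adjusted over the list alone), but as a list it passed (adjusted p = 0.00147 preset, 0.0475 estimated), with noto at 1.84 ± 0.53, adjusted p = 0.145. Ventral genes were 2 up and 0 down (adjusted p = 5.89e-05 preset, 0.0532 estimated), and Pou5f3-dependent regulators 0 up and 2 down (adjusted p = 0.00147 preset, 0.0176 estimated). Immediate-early genes (1 up, 0 down, adjusted p = 0.0169 preset, 0.374 estimated) and ribosomal genes (0 up, 1 down, adjusted p = 0.00128 preset, 0.496 estimated) lost their call with that correlation. More genes rose than fell with scaling to the 75th percentile (77 and 49), processed signals (138 and 93) and the authors' values (133 and 94). The fit within slide 4 passed 12 genes, and leaving out GFP replicate 1 or Klf2b replicate 2 gave 104 and 468.

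With Klf2b in WT under cycloheximide (slide 3 against slide 4), 45 genes rose and 22 fell. The keratin genes krt5 (3.95 ± 0.51), krt97 (3.72 ± 0.41), krt4 (3.40 ± 0.38) and krt8 (2.55 ± 0.32) led, and enveloping-layer genes were 6 up and 0 down of 20 (8 and 0 adjusted over the list alone, adjusted p = 1.39e-20 preset, 0.00117 estimated). The Klf2b duplicates of these 4 keratin genes differed widely, with SDs of 1.72, 1.07, 1.45 and 0.92 in that order. The stress gene sesn3 (-2.91 ± 0.53), bbc3 (-2.34 ± 0.42), fosab (-2.20 ± 0.32), tas2r202 (-1.97 ± 0.26) and gadd45aa (-1.85 ± 0.34) fell most. Their Klf2b SDs were, in order, 1.26, 0.67, 1.09, 0.08 and 0.36. Standard errors rest on all groups and do not show this. The p53 list gave 0 up and 2 down of 9 (0 and 3 adjusted over the list alone, adjusted p = 1.49e-09 preset, 0.0174 estimated). Ribosomal genes had 0 rises and 0 falls of 85 in limma's test (1 and 1 adjusted over the list alone), a median of 0.27, and adjusted p = 1.21e-08 preset, 0.474 estimated. Without Klf2b replicate 2 the count was 1327 and without GFP replicate 2 18, and GFP replicate 1 and Klf2b replicate 1 left out gave 31 and 25. With MZspg 10 rises and 4 falls were shared (0.154 and 0.0948 expected), with r of 0.0408 across genes, below 0.0738 in simulated unchanged groups.

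Without cycloheximide, Klf2b in WT on slide 1 raised 526 genes and lowered 682. The chloride channel gene clic2 (3.80 ± 0.37), arl3l1 (3.18 ± 0.50) and icn (3.02 ± 0.47) rose most, and her1 (-3.53 ± 0.38), sp5l (-3.45 ± 0.54), dhrs3b (-3.31 ± 0.27), sox2 (-2.80 ± 0.35) and her7 (-2.72 ± 0.45) fell most. Dorsal genes gave 0 up and 6 down of 17 (1 and 7 adjusted over the list alone), including foxa2 (-1.61 ± 0.35) and lhx1a (-1.10 ± 0.19) (adjusted p = 5.27e-05 preset, 0.0135 estimated). Pou5f3-dependent regulators were 0 up and 5 down of 9 (0 and 6 adjusted over the list alone, adjusted p = 9.31e-06 preset, 0.000258 estimated), with foxd3 at -1.07 ± 0.28, adjusted p = 0.0313. Mesendoderm genes gave 0 up and 5 down of 22 (1 and 7 adjusted over the list alone), with msgn1 at -2.01 ± 0.28 (adjusted p = 0.000328 preset, 0.252 estimated). Enveloping-layer genes (0 up, 2 down, adjusted p = 0.0132 preset, 0.404 estimated) and p53 genes (0 up, 1 down, adjusted p = 0.0291 preset, 0.404 estimated) did not hold with that correlation. The fit within slide 1 passed 24 genes, scaling to the 75th percentile 290, and leaving out GFP replicate 1 or 2 gave 615 and 236.

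For Klf2b in MZspg without cycloheximide (slide 3 against slide 1) 12429 genes passed, with 40.9% of the testable genes having probes that disagreed. The enveloping-layer list gave 12 up and 1 down (adjusted p = 0.0598 preset, 0.757 estimated), and clic2 (5.11 ± 0.37) and cavin2b (5.30 ± 0.27) rose. Shared with cycloheximide were 57 rises (24.1 expected) and 29 falls (23.2 expected) in MZspg, where 11 and 4 genes went opposite ways, and 11 rises (1.05 expected) and 3 falls in WT.

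Klf2a and Klf2b were compared directly, each pair on 1 slide, to ask where the related factors differ. In MZspg under cycloheximide 234 genes were higher with Klf2a and 103 with Klf2b. Higher with Klf2a were krt5 (3.93 ± 0.48, adjusted p = 0.00013), nnr (2.97 ± 0.34), lfng (2.51 ± 0.31) and foxa3 (2.38 ± 0.41), and higher with Klf2b were prkcba (-2.60 ± 0.22), oc90 (-2.60 ± 0.51) and amotl2b (-2.59 ± 0.42). Enveloping-layer genes were higher with Klf2a in 9 cases and lower in 0 of 20 (12 and 0 adjusted over the list alone), as evpla (1.87 ± 0.27) and capn9 (2.32 ± 0.36) (adjusted p = 3.75e-18 preset, 0.00158 estimated). The mesendoderm (7 and 0 of 22, adjusted p = 2.35e-14 preset, 0.00158 estimated), dorsal (2 and 0 of 17, adjusted p = 2.72e-08 preset, 0.000705 estimated) and ventral lists (4 and 0 of 25, adjusted p = 6.65e-08 preset, 0.0093 estimated) were also higher with Klf2a. In MZspg without the drug 235 genes were higher with Klf2a and 49 with Klf2b, led by neff1 (3.45 ± 0.33), casq1b (3.33 ± 0.25) and anxa2a (3.19 ± 0.47) and by oc90 (-2.77 ± 0.51). The enveloping-layer test did not hold with the estimated correlation (adjusted p = 5.47e-10 preset, 0.073 estimated). In WT 486 genes were higher with Klf2a, such as anxa2a (3.74 ± 0.47) and stat1b (3.40 ± 0.20), and 829 with Klf2b, such as rtn2b (-2.41 ± 0.69), and 4 enveloping-layer genes were higher with Klf2a (adjusted p = 0.000134 preset, 0.329 estimated). The rtn2b duplicates had an SD of 2.57 with Klf2b and 0.19 with Klf2a. In WT under cycloheximide only 12 and 2 genes passed, led by ociad2 (2.06 ± 0.34). The p53 list was higher with Klf2a (0 and 0 in limma's test of each gene, 4 and 0 adjusted over the list alone, adjusted p = 2.06e-11 preset, 0.0119 estimated).

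These counts rest on single samples. In MZspg under cycloheximide the count was 150 without Klf2a replicate 2 and 17 in the within-slide fit. In MZspg without the drug it was 176 and 153 without Klf2a replicate 1 or 2 and 153 within the slide. In WT it was 3435 without Klf2b replicate 1, 225 without Klf2b replicate 2, 213 without Klf2a replicate 2 and 65 within the slide. Its split of 486 and 829 turned to 82 and 10 with scaling to the 75th percentile, 41 and 15 with loess, 572 and 271 with processed signals and 582 and 286 with the authors' values. In WT under cycloheximide it was 49 and 3 without Klf2a replicate 1 or 2, 24 and 481 without Klf2b replicate 1 or 2, and 2 within the slide. Both factors' effects against GFP share the GFP samples, so their likeness is partly built in. The r across genes was 0.677 under cycloheximide in MZspg (0.571 in simulated unchanged groups), 0.693 in WT (0.567), 0.624 without the drug in WT (0.569) and 0.966 in MZspg (0.571). The covariances were 0.0925 (0.0354 simulated), 0.0578 (0.0349) and 0.108 (0.0353) for the first 3 of these, and part of each excess may come from the shared controls.

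FoxD3 and GFP were compared in WT under cycloheximide (slide 2 against slide 4), with 865 genes up and 899 down. The histone gene h2ax (3.61 ± 0.43, adjusted p = 1.96e-05), rhoq (2.88 ± 0.18) and nsg2 (2.71 ± 0.24) rose most after foxd3. The genes sesn3 (-3.80 ± 0.53), sp5l (-3.57 ± 0.54), slc25a55a (-3.47 ± 0.30), apoeb (-3.34 ± 0.36) and lft2 (-3.25 ± 0.25) fell most. Among regulators klf17 (-1.42 ± 0.23, adjusted p = 0.000661) and klf2a (-1.98 ± 0.27, adjusted p = 0.00012) fell. Mesendoderm genes gave 2 up and 9 down of 22 (3 and 10 adjusted over the list alone), with the Nodal gene ndr1 at -1.89 ± 0.20, aplnrb at -2.64 ± 0.31 and the notochord and mesoderm gene tbxta at -2.89 ± 0.46 (adjusted p = 2.16e-09 preset, 0.0541 estimated). Of the p53 genes 0 rose and 4 fell of 9, such as gadd45aa (-3.12 ± 0.34), bbc3 (-2.59 ± 0.42) and phlda3 (-2.75 ± 0.45) (adjusted p = 1.69e-06 preset, 0.105 estimated). Dorsal genes (1 up and 4 down of 17, adjusted p = 0.0196 preset, 0.278 estimated) and ribosomal genes (9 up and 2 down of 85, adjusted p = 2.33e-05 preset, 0.453 estimated) passed only with the preset correlation. Enveloping-layer genes were 3 up and 2 down (adjusted p = 0.204), with krt8 at 1.60 ± 0.32. Leaving out FoxD3 replicate 1 or 2 gave 547 and 539 genes, and GFP replicate 1 or 2 gave 630 and 553, while scaling to the 75th percentile gave 821.

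In MZspg under cycloheximide FoxD3 raised 961 genes and lowered 743, again across slides 2 and 4. The Hairy-related gene her2 (4.28 ± 1.15, adjusted p = 0.0258), h2ax (3.63 ± 0.43, adjusted p = 2.66e-05), mia (3.15 ± 0.62) and aplnrb (2.87 ± 0.31) rose, as did the main pou5f3 probe (0.72 ± 0.20, adjusted p = 0.0329). A second pou5f3 probe, well above background in both groups, lay at 8.62 log2 with FoxD3 and 8.55 with GFP. The genes capn5a (-3.18 ± 0.25), gatm (-3.17 ± 0.29) and apoeb (-2.48 ± 0.36) fell. As in WT, lft2 fell (-2.13 ± 0.25). The only lists that held with the estimated correlation contain foxd3 itself, the injected genes (adjusted p = 4.4e-13 preset, 3.12e-10 estimated) and Pou5f3-dependent regulators (adjusted p = 3.02e-06 preset, 9.31e-05 estimated). Mesendoderm genes were 2 up and 3 down (adjusted p = 0.174), dorsal genes 3 up and 2 down (adjusted p = 0.602), with foxa3 at 2.27 ± 0.44, and ribosomal genes 4 up and 0 down (adjusted p = 0.019 preset, 0.739 estimated). With WT, without shared samples, 351 rises (36.9 expected) and 291 falls (29.7 expected) were in common, with r of 0.531 across genes (0.136 simulated). Both comparisons set slide 2 against slide 4 on the same arrays. The expected counts and the simulation hold no slide difference, so a shared FoxD3 response cannot be told apart from one. Without FoxD3 replicate 1 or 2 the counts were 533 and 418, without GFP replicate 1 or 2 they were 502 and 1056, and with scaling to the 75th percentile 764.

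Without cycloheximide FoxD3 (slide 2) against GFP (slide 1) gave 6775 genes up and 5380 down in WT and 8104 and 5847 in MZspg, with 18.6 and 34.3% of testable genes having probes that disagreed. In WT the largest falls were the keratin genes cyt1 (-6.79 ± 0.28, at least 110-fold), krt92 (-6.29 ± 0.35) and krt5 (-6.19 ± 0.51) and the antifreeze-like gene afp4 (-6.62 ± 0.48). The maternal genes btg4 (4.77 ± 0.43) and arl4aa (4.08 ± 0.25) were among the largest rises. Enveloping-layer genes were 2 up and 17 down of 20 (adjusted p = 5.77e-14 preset, 0.00637 estimated). Yolk syncytial genes were 1 up and 8 down of 11, with hnf4a at -4.09 ± 0.20 and mttp, for lipoprotein assembly, at -5.34 ± 0.26 (adjusted p = 3.23e-08 preset, 0.00307 estimated). Maternal genes gave 12 up and 0 down of 15 (adjusted p = 7.76e-05 preset, 0.00307 estimated). Adhesion genes were 2 up and 7 down (adjusted p = 0.0136 preset, 0.02 estimated), and mesendoderm genes 2 up and 15 down, with sox32 at -5.02 ± 0.29 (adjusted p = 1.11e-06 preset, 0.0594 estimated). Ventral (adjusted p = 0.0136 preset, 0.23 estimated), dorsal (adjusted p = 0.0136 preset, 0.132 estimated), Pou5f3-dependent (adjusted p = 0.0233 preset, 0.0885 estimated) and ribosomal genes (adjusted p = 0.023 preset, 0.666 estimated) were lower with the preset correlation alone. In MZspg the yolk syncytial list held (1 up, 9 down, adjusted p = 1.3e-05 preset, 0.0333 estimated), with apoeb at -7.14 ± 0.36. The others did not, with enveloping-layer genes 3 up and 14 down (adjusted p = 0.00359 preset, 0.41 estimated) and mesendoderm genes 3 up and 14 down (adjusted p = 0.00359 preset, 0.358 estimated). Shared with the cycloheximide comparison were 432 rises (260 expected) and 360 falls (215 expected) in WT, and 574 rises (346 expected) and 212 falls (193 expected, p = 0.0586, Fisher's exact test) in MZspg. Many genes went opposite ways, 245 up and 116 down without the drug in WT, and 249 and 147 in MZspg.

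Cycloheximide was compared with no drug in GFP-injected embryos to ask which transcripts need new protein by 30% epiboly, across slides 4 and 1. In WT 7154 genes were higher and 6396 lower, and in MZspg 7856 and 6313, with 19.3 and 29.4% of testable genes having probes that disagreed. The maternal decay gene btg4 rose in WT (6.87 ± 0.43, adjusted p = 3.38e-11) and MZspg (5.59 ± 0.43, adjusted p = 5.07e-10), and in WT also arl4aa (5.46 ± 0.25), the lipase gene lipg (5.39 ± 0.33) and gadd45aa (4.84 ± 0.34). The largest falls in WT were afp4 (-8.12 ± 0.48, at least 268-fold), krt5 (-7.79 ± 0.51), krt92 (-7.74 ± 0.35), cyt1 (-7.12 ± 0.28) and cyt1l (-7.07 ± 0.28). In MZspg afp4 fell too (-7.16 ± 0.48), while mbtps2 (-7.68 ± 0.32), plp2b (-7.41 ± 0.22), gxylt2 (-7.30 ± 0.22) and ano10b (-7.28 ± 0.20) fell more. Probes of the regulators disagreed here. The main klf2a probe rose in WT (2.07 ± 0.27, adjusted p = 1.4e-06) and a second fell (-0.54 ± 0.20, adjusted p = 0.0268), while in MZspg both fell (-1.04 ± 0.27 for the main one). The main klf17 probe rose in WT (1.38 ± 0.23) and MZspg (1.08 ± 0.23), but 2 others fell in WT (-0.99 ± 0.19 and -0.66 ± 0.18) and did not pass in MZspg, where loess (-0.29) and scaling to the 75th percentile (-0.45) also turned the main one. For the main klf17 probe 0 of the MZspg GFP samples without the drug were well above background, so the size of its change there is uncertain. Of the genes that rose in WT 2537 also rose with the drug in both Klf2a- and Klf2b-injected MZspg embryos, away from slide 1, and of those that fell 1846 did so. For MZspg these numbers were 2468 and 1661.

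Enveloping-layer genes gave 3 up and 17 down of 20 in WT, with a median of -4.72 (adjusted p = 5.14e-13 preset, 0.0143 estimated), and 3 up and 15 down in MZspg (adjusted p = 0.000454 preset, 0.291 estimated). Yolk syncytial genes were 1 up and 8 down of 11 in WT, such as hnf4a (-4.15 ± 0.20) and mttp (-5.52 ± 0.26) (adjusted p = 8.21e-05 preset, 0.038 estimated), and 1 up and 7 down in MZspg (adjusted p = 0.000454 preset, 0.179 estimated). Maternal genes were higher, 11 up and 2 down of 15 in WT, with dazl at 4.21 ± 0.19 and mos at 4.11 ± 0.29 (adjusted p = 8.94e-05 preset, 0.0068 estimated), and 9 up and 2 down in MZspg (adjusted p = 0.0154 preset, 0.179 estimated). Germ plasm genes (6 up and 1 down of 8, adjusted p = 0.0196 preset, 0.143 estimated) and mesendoderm genes (3 up and 15 down of 22, adjusted p = 0.0196 preset, 0.413 estimated) passed in WT with the preset correlation alone. So did ribosomal genes, with 3 up and 75 down of 85 (adjusted p = 2.77e-09 preset, 0.252 estimated). In MZspg the ventral (1 up, 14 down, adjusted p = 0.000748 preset, 0.212 estimated), mesendoderm (2 up, 14 down, adjusted p = 0.00401 preset, 0.308 estimated) and ribosomal lists (5 up, 59 down, adjusted p = 0.000454 preset, 0.503 estimated) behaved alike, and none of the MZspg lists held. Among FoxD3-injected samples, all on slide 2, the drug changed 2298 genes in WT (880 up, 1418 down, 16.1% of testable genes with probes that disagreed) and 1 in MZspg in the limma test (chrna4b, -0.87, named after its value was seen). In MZspg 505 of 22511 genes had an unadjusted p under 0.05, fewer than that threshold would give by chance in unchanged genes. With scaling to the 75th percentile the median of all genes fell by 0.91 in WT and by 1.07 in MZspg, so these directions are relative to the whole array.

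To ask whether the injected factors raise what MZspg embryos lack, the median effect in MZspg was taken over the 2047 genes lower in MZspg under cycloheximide. It was 0.26 for Klf2a (738 genes up, 295 down), 0.24 for Klf2b (700 up, 304 down) and 0.08 for FoxD3 (627 up, 517 down). Against all other genes Klf2a passed with the preset correlation (p = 0.0266) but not with an estimated one (p = 0.242), and Klf2b (p = 0.0663 and 0.332) and FoxD3 (p = 0.488 and 0.714) did not pass. These values set slide 3 or 2 against slide 1. Over the 3288 genes lower in MZspg among FoxD3-injected embryos the medians were -0.21 for Klf2a (p = 3.01e-09 with the preset and 0.0102 with the estimated correlation) and -0.24 for Klf2b (p = 2.15e-10 and 0.00592). The MZspg FoxD3 samples behind this list differed from their treated counterparts in 1 gene. A mix-up or drug treatment of them would enter the list, which then need not hold genes that depend on Pou5f3. Within slide 4 and under cycloheximide 112 of these 3288 genes rose and 47 fell with Klf2a, and 24 rose and 20 fell with Klf2b. The medians there were -0.08 for Klf2a (p = 0.503 with the preset and 0.771 with the estimated correlation) and -0.07 for Klf2b (p = 0.0725 and 0.436). The 3844 genes lower in MZspg with GFP and no drug also share no sample with slide 4. Of these 186 rose and 39 fell there with Klf2a (median 0.04, p = 0.000561 with the preset and 0.0437 with the estimated correlation). With Klf2b 35 rose and 14 fell (median 0.02, p = 0.0564 with the preset and 0.265 with the estimated correlation).

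Whether the injection effects differ between genotypes was tested as interactions without cycloheximide. For FoxD3, where slide differences cancel only if alike in both genotypes, 19.3% of testable genes had probes that disagreed. There 6335 genes passed (2998 up, 3337 down), including foxd3 (3.90 ± 0.37) and klf2a (-1.24 ± 0.36), and 4187 or 4196 passed without MZspg GFP replicate 1 or MZspg FoxD3 replicate 1. Scaling to the 75th percentile gave 2417 up and 10960 down. The MZspg FoxD3 samples differed from their treated counterparts in 1 gene (2298 in WT), so a mix-up or drug treatment of them would enter this count. Effects were more positive in MZspg for rabgap1l2 (5.28 ± 0.31), krt99 (5.03 ± 0.35) and her1 (4.28 ± 0.50), and more negative for cfd (-4.77 ± 0.62) and the BMP gene admp (-3.32 ± 0.38). Pou5f3-dependent regulators gave 5 up and 1 down of 9 (adjusted p = 1.18e-06 preset, 9.14e-05 estimated) and enveloping-layer genes 13 up and 0 down (adjusted p = 2.12e-07 preset, 0.164 estimated). The Pou5f3-dependent list contains the injected foxd3 itself, which is among its rises. For Klf2a and Klf2b, whose MZspg samples lie on another slide than their controls, 9605 and 10993 genes passed, 38.0 and 39.7% of testable genes had probes that disagreed. Enveloping-layer genes were 11 up and 1 down for Klf2a (adjusted p = 0.000407 preset, 0.904 estimated) and 12 up and 1 down for Klf2b (adjusted p = 0.00969 preset, 0.822 estimated).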

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

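All the tests weighed in this part were chosen only after the results were seen, except the interaction tests. A difference between genotypes in the response was found for cycloheximide (3352 genes), Klf2a (9605), Klf2b (10993) and FoxD3 (6335). The Klf2a and Klf2b counts set slide 3 against slide 1 in MZspg but not in WT. The FoxD3 count would hold any mix-up or drug treatment of the MZspg FoxD3 samples, which differed from their treated counterparts in 1 gene.

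Slide 1 stood apart in 940 genes. Dim signal as the whole cause is argued against, since the WT FoxD3 samples, with mean net signals of 934 and 1102 against 327 to 1390 on slide 1, scored -0.0217 on the probe component, below 0.237 to 0.365, although they scored highest outside slide 1, so a part is open. Probes of 1 gene would move together if only the level of a single transcript changed, yet the lowest slide 1 score lay 0.2514 above the highest of the other slides. Probes also disagreed within slide 2 alone, in 16.1% of testable genes for cycloheximide in WT and 15.4% for genotype without the drug. The score goes with different labelling, hybridisation or scanning of slide 1, without singling it out. A state shared by these 4 groups alone cannot be told apart from this, since 0 groups were measured on slide 1 and on another slide. Differences between slide 1 and the others may therefore be technical for many genes, which of them is open.

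Genes that cycloheximide lowers were low in FoxD3-injected embryos without the drug, since of 239 genes at least 4-fold lower under cycloheximide in both Klf2a- and Klf2b-injected MZspg embryos, 192 were lower with FoxD3 than GFP in WT (median -2.15) and 184 in MZspg (median -1.84). Slide 1 as the whole cause is argued against, since genes at least 4-fold lower under the drug in Klf2a-injected MZspg embryos, picked on 1 pair of arrays, had medians of -1.9484 (489 genes) and -1.6066 (216 genes) between FoxD3 and Klf2b in MZspg on other arrays of slides 2 and 3 (upper quartiles -1.21 and -0.93), although slide 3 served in both steps. A cycloheximide treatment of the WT FoxD3 samples is left open and cannot be told apart, since 2298 genes parted them from their treated counterparts (16.1% of testable genes with probes that disagreed), but of the 239 genes only 14 fell there (median -0.26), against 203 with GFP (median -2.91). In MZspg only 1 gene differed, so a mix-up or treatment of those samples may account for part of it. That injected FoxD3 holds these genes back may also account for part and cannot be tested, as 0 GFP-injected groups lay on the FoxD3 slide, and of 97 genes that the drug raised likewise 94 rose with FoxD3 in WT (median 2.69) and 94 in MZspg (median 2.49).

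Keratin and other enveloping-layer genes rose with Klf2a under cycloheximide in MZspg. A larger share of enveloping-layer cells cannot be told apart from a change within them, since only 1 member well above background in both GFP samples fell, klf17 (-1.17), which was low in MZspg and ended near background. Keratin transcripts binding the probes of related keratins is argued against as the whole cause, since 3 members that are not keratins (capn9, cldnb and evpla) of 10 also rose. Of the 11 members that rose in MZspg 8 also rose in WT, against other GFP samples, which is consistent with Klf2a raising these genes without newly made proteins. This is a hypothesis found and tested on the same data, and lasting protein made before the drug took effect was not tested.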

How the results depend on the processing

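Alternatives without the 4 groups that lie apart (FoxD3 in both genotypes, Klf2a and Klf2b in MZspg, none with the drug) and with cycloheximide compared among FoxD3-, Klf2a- or Klf2b-injected samples were chosen only after the results were seen. The others were fixed before the data were seen. Of 33 counts, medians and overlaps, recomputed 485 times, 362 values kept their direction and side of the threshold, or stayed within 1.5 times for counts, and 7 of the 33 did so under all alternatives fixed beforehand. Of 271 named gene comparisons, recomputed 3466 times, 3242 kept direction and side, 212 lost their call, 1 gained one and 11 turned, most of them near 0. Where not said otherwise, the cause was not tested. CHX stands for cycloheximide below, a factor for its count of genes against GFP, and the value reported above is in brackets.

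Scaling to the 75th percentile gave Klf2a 98 (1103) and Klf2b 290 (1208) in WT, and Klf2a against Klf2b 92 (1315) in WT and 29 (14) in WT CHX. Klf2a in MZspg CHX gave 558 (872), Klf2b in WT CHX 36 (67), and FoxD3 821 (1764) in WT CHX and 764 (1704) in MZspg CHX. The interactions gave 16544 (10993) for Klf2b and 13377 (6335) for FoxD3. Overlaps with and without CHX were 16 (39) for Klf2a, 5 (14) for Klf2b and 376 (792) for FoxD3 in WT and 403 (786) for FoxD3 in MZspg. The median over genes lower in MZspg turned to -0.46 (0.08) for FoxD3, and that of Klf2b passed at 0.12 (0.24). Calls of medians here are with the preset correlation, and with the estimated one only those of Klf2a and Klf2b over genes picked without CHX passed, on the GFP arrays (p = 9.75e-06 and 0.000182) and, turned, on the FoxD3 arrays. This scaling leaves the median of all genes free, and it moved by -0.91 for cycloheximide in WT and -1.07 in MZspg. For Klf2a, Klf2b and FoxD3 in MZspg it was -0.72, -0.70 and -0.98, and for their interactions -0.72, -1.01 and -0.75. It was 0.31 between genotypes, 0.33 for Klf2b in WT, -0.31 for Klf2a against Klf2b in WT, 0.21 for Klf2b in MZspg CHX, and between -0.19 and 0.10 elsewhere, so changes of lists below these sizes depend on the scaling.

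With that scaling cycloheximide raised 4718 and lowered 12303 genes in WT (7154 and 6396), and 5328 and 12781 in MZspg (7856 and 6313). In MZspg the splits were 5276 and 11158 for Klf2a (6911 and 5423), 5223 and 11048 for Klf2b (7052 and 5377) and 5640 and 12396 for FoxD3 (8104 and 5847). Interactions gave 4367 and 8910 for Klf2a (5129 and 4476), 4882 and 11662 for Klf2b (6055 and 4938) and 2417 and 10960 for FoxD3 (2998 and 3337). In MZspg CHX they were 427 and 131 for Klf2a (551 and 321) and 77 and 49 for Klf2b (77 and 97), and in WT 81 and 17 for Klf2a (686 and 417) and 40 and 250 for Klf2b (526 and 682). Klf2a against Klf2b split 82 and 10 in WT (486 and 829) and 136 and 57 in MZspg (235 and 49). Of the shared calls 248 and 155 were rises and falls for FoxD3 in MZspg (574 and 212), and 5 and 0 for Klf2b in WT (11 and 3). Genes that turned were klf17 under the drug in MZspg (-0.45), klf2b between genotypes (-0.29, no call as reported) and pou5f3 with Klf2a in MZspg (0.67), which had no call as reported and passed here (adjusted p = 0.0274). Without a call in either, so did klf2a with Klf2a in WT (-0.014) and klf2b with Klf2b in WT (-0.18).

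Loess within and quantile between arrays gave 5119 genes between genotypes (8055), Klf2b 647 in WT (1208), and Klf2a against Klf2b 56 in WT (1315) and 63 in WT CHX (14). The Klf2a median fell below the test at 0.14 (0.26) and the FoxD3 median turned to -0.078 (0.08), as did klf17 under the drug in MZspg (-0.29) and pou5f3 with Klf2a in MZspg (0.023). Splits moved to 32 and 35 for Klf2b in WT CHX (45 and 22), 41 and 15 for Klf2a against Klf2b in WT, and 10 and 5 for the Klf2b overlap in WT.

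Processed signals and the authors' values moved alike. Klf2a against Klf2b in WT gave 843 and 868 (1315), Klf2b overlaps 26 and 24 in WT (14) and 131 and 131 in MZspg (86), and the Klf2a median lost its call at 0.40 and 0.38 (0.26). Their splits were 1166 and 421, and 1120 and 408, for Klf2a in WT. Klf2b gave 72 and 13, and 71 and 13, in WT CHX, and 138 and 93, and 133 and 94, in MZspg CHX. Klf2a against Klf2b gave 572 and 271, and 582 and 286, in WT, and 145 and 68, and 149 and 63, in MZspg. The FoxD3 overlap in MZspg gave 447 and 306, and 455 and 303. The median of all genes lay up to 0.30 higher, for FoxD3 in MZspg.

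No filter let the Klf2b median pass at 0.23. No dye term did so too (0.23). Without a dye term and with samples of 1 array as independent, Klf2a against Klf2b gave 800 and 797 in WT, 7 and 9 in WT CHX, and 195 and 207 in MZspg CHX (337). The fit within a slide has 3 residual degrees of freedom, which can cost calls, but it raised the genotype count with CHX to 5929 (4376). It gave Klf2a 215 and Klf2b 24 in WT, Klf2a 84 and Klf2b 12 in MZspg CHX (174), and Klf2a against Klf2b 65 in WT, 2 in WT CHX, 153 in MZspg (284) and 17 in MZspg CHX. Genes lower in MZspg without CHX, picked with the GFP samples of the comparison itself, gave medians of 0.55 for Klf2b and 0.29 for FoxD3, which passed, FoxD3 not with the estimated correlation (p = 0.0999). Genes picked on the FoxD3 arrays turned them to -0.21 for Klf2a and -0.24 for Klf2b. Without the 4 groups that lie apart Klf2b in WT gave 797, Klf2a against Klf2b in WT CHX 9 and the Klf2b overlap in WT 9. Cycloheximide changed 2298 genes in WT (13550) and 1 in MZspg (14169) among FoxD3-injected samples, and in MZspg 7276 among Klf2a- and 6395 among Klf2b-injected ones, which avoid slide 1.

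With the replicate block (the number 1 or 2 of the labels as a term) all 33 results stayed within the limits above, such as 850 genes for Klf2a in MZspg CHX (872) and 7977 between genotypes (8055), and of named genes only tat, with Klf2a in WT CHX, lost its call. Deviations of samples with the same number had r of -0.63 to 0.60 over 120 pairs of groups (median 0.026), 29 of them over 0.1 and 27 under -0.1. Equal numbers share an array in 8 of these pairs, and no pairing across all groups was seen.

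Leaving out 1 sample, which leaves fewer samples, gave 4950 to 6523 genes between genotypes and 2066 to 2929 with CHX, 11525 to 12041 for cycloheximide in WT and 12322 to 12675 in MZspg. Klf2a gave 314 to 1069 in WT, 44 to 111 in WT CHX, 10238 to 10960 in MZspg and 301 to 845 in MZspg CHX. In the same order Klf2b gave 236 to 1604, 18 to 1327, 10213 to 11125 and 104 to 468, FoxD3 10032 to 10758, 539 to 630, 11791 to 12451 and 418 to 1056, and Klf2a against Klf2b 213 to 3435, 3 to 481, 153 to 364 and 150 to 505. Interactions ranged from 1793 to 2882 for cycloheximide, 7878 to 8783 for Klf2a, 9453 to 10771 for Klf2b and 4187 to 5615 for FoxD3. Medians lay at 0.25 to 0.33 for Klf2a, 0.20 to 0.29 for Klf2b, which passed without Klf2b replicate 1 (0.29) or MZspg GFP CHX replicate 1 (0.24), and 0.014 to 0.11 for FoxD3. Overlaps were 16 to 32 for Klf2a in WT and 164 to 419 in MZspg, 3 to 145 and 53 to 172 for Klf2b, and 280 to 717 and 236 to 742 for FoxD3. The reported value near 0 turned for pou5f3 with Klf2a in MZspg (0.038 and 0.15) and klf2a with Klf2a in WT (-0.19 and -0.20).

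Signal over background limits the genes that can be seen, since 54.2 to 74.3% of spots were well above it. A change of a gene near background in a group is a lower bound only where the other group was well above background. Where both groups were near background the change has no such bound, as for krt17 and evpla between genotypes under cycloheximide. The interactions of these genes are therefore not lower bounds.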

Other observations

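The gene choices in the first paragraph, the comparisons in the first and second, and every test in this part were made only after values were seen. Away from slide 1, cycloheximide in Klf2a-injected MZspg embryos (slide 4 against slide 3) lowered genes of the yolk syncytial layer, the tissue between yolk and embryo, with 0 up and 7 down of 11 (adjusted p = 3.75e-11 preset, 0.000233 estimated). The largest falls were afp4 (-6.01 ± 0.48), the apolipoprotein gene apoeb (-5.43 ± 0.36), plekhf1 (-5.25 ± 0.30) and the endoderm gene gata6 (-5.22 ± 0.37), and the largest rises btg4 (3.45 ± 0.43), hsd3b7 (3.22 ± 0.39) and trmt9b (3.14 ± 0.22). Enveloping-layer genes were 1 up and 16 down of 20 (adjusted p = 6.57e-18 preset, 0.0018 estimated), and maternal genes 8 up and 3 down of 15 (adjusted p = 6.56e-05 preset, 0.00213 estimated). Germ plasm genes were 5 up and 1 down of 8 (adjusted p = 0.00255 preset, 0.0496 estimated) and adhesion genes 1 up and 7 down of 14 (adjusted p = 0.00222 preset, 0.00303 estimated). Ribosomal genes were 2 up and 58 down of 85, without holding (adjusted p = 4.65e-10 preset, 0.174 estimated). Only 3.89% of testable genes had probes that disagreed here, against 29.4% in the GFP comparison of MZspg. In Klf2b-injected MZspg embryos afp4 (-6.48 ± 0.48), apoeb (-5.84 ± 0.36) and the cytokine gene il34 (-5.76 ± 0.38) fell.

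Within the FoxD3 slide, MZspg embryos differed from WT in 6547 genes without and 3280 with cycloheximide, with 15.4 and 3.08% of testable genes having probes that disagreed. The comparison without the drug would hold any mix-up or drug treatment of the MZspg FoxD3 samples. The falls of sult6b1 (-5.20 ± 0.34 and -4.69 ± 0.34), vgll4l (-4.35 ± 0.33 and -4.06 ± 0.33) and nnr (-4.21 ± 0.34 and -4.79 ± 0.34) were among the largest in both, as were the rises of sccpdha.2 (4.79 ± 0.79 and 3.89 ± 0.79) and gbgt1l4 (4.28 ± 0.50 and 3.60 ± 0.50). The falls of spag7 (-6.26 ± 1.18 and -6.46 ± 1.18) and zdhhc16a (-4.47 ± 0.13 and -4.22 ± 0.13) were of similar size. Stress-related genes chosen for their values were higher in MZspg there, phlda3 (2.27 ± 0.42 and 1.84 ± 0.42), gadd45aa (1.84 ± 0.31 and 1.80 ± 0.31), bbc3 (1.79 ± 0.39 and 1.58 ± 0.39) and fosab (2.04 ± 0.30 and 1.95 ± 0.30), whereas with GFP under cycloheximide bbc3 was lower in MZspg (-2.30 ± 0.39), a contrast that was not tested. The p53 list rose in 6 and fell in 0 of 9 cases without the drug (adjusted p = 0.0411 preset, 0.371 estimated). Under cycloheximide 987 rises and 992 falls were shared with the GFP comparison (177 and 142 expected from independence), and 10 and 26 went the other way. Without the drug 907 rises and 1068 falls were shared (610 and 561 expected), with 558 and 327 opposite, and r was 0.312 across genes.

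The 239 genes lowered by cycloheximide away from slide 1 had a median level of 11.62 log2 in WT GFP, 11.45 in MZspg Klf2a, 10.86 in MZspg Klf2b and 10.49 in MZspg GFP samples. They lay at 8.63 in WT FoxD3 and 7.84 in MZspg FoxD3 samples, and at 7.21 to 8.83 in the cycloheximide groups. On an axis from no drug (0) to cycloheximide (1) in GFP-injected samples, MZspg FoxD3 samples lay at 0.893 ± 0.042 and WT FoxD3 at 0.750 ± 0.032 (SD, n = 2), MZspg Klf2a at 0.593 and MZspg Klf2b at 0.654. This axis also runs from slide 1 to slide 4, and the other untreated groups of slide 1 lay near its start, WT Klf2a at 0.0938 and WT Klf2b at -0.0119. Without shared samples, FoxD3 in MZspg and cycloheximide in WT had r of 0.832 across genes (0.0706 in simulated unchanged groups), although both set slide 1 against another slide. The first principal component held 62.6% of the variance of all samples. Gene signal over spike-in signal, relative to the mean of all samples of a dye, was 0.493 in MZspg GFP, 0.493 in WT Klf2b and 0.662 in WT Klf2a, and 1.18 to 2.02 in the cycloheximide groups except WT Klf2b at 0.916. The 2 samples of WT Klf2b with cycloheximide differed widely, with an SD of 0.931 log2. WT GFP lay at 0.840, WT FoxD3 at 0.553, MZspg Klf2a at 0.989 and MZspg Klf2b at 0.697. MZspg FoxD3 lay 0.59 log2 above the mean, within the range of treated groups.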
